A study of Mus musculus with 8 samples.

How the data were processed

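Expression was measured on Affymetrix mouse 3′ expression arrays, 1 array per pooled islet RNA sample, with 4 arrays per group and 8 in all. Per the labels' protocols, biotin-labelled target was made from Trizol-extracted total RNA with the Affymetrix IVT Express kit. The deposited values are log2 expression values that the authors made with RMA in R 2.8.0, per the submitters' processing notes. RMA subtracts background, normalizes between arrays and summarises the probes of each probe set. The package, its options and the chip definition are not given in the sources used here. The log2 values ran from 2.68 to 15.02 over arrays with medians from 4.79 to 4.90. Where RMA aligned the arrays' distributions, a shift shared by most genes cannot be seen, and differences near both ends of the range are compressed. The upper quartile of KsJ_HF replicate 3 was 6.22 against 6.49 to 6.58 in the others and its SD 1.83 against 1.94 to 2.00, so it was not fully aligned with them. No scanner values were analysed here.

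The table held 45101 probe sets, of which 64 control probe sets were set aside and 45037 tested. Genes were named through the platform annotation, in which 34958 probe sets carried 1 gene symbol, 932 several, and 9211 were not listed. Of the first, 34754 matched by Entrez number to the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names only. No gene was named from a probe set with several symbols. For lists, 10 members were looked up under a newer symbol, each with the older one among the table's synonyms.

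Groups and replicate numbers came from the sample titles. The series design states biological replicates, and each sample pooled at least 3 mice. No arrays were identical. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided) on the log2 values with group as the only term, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 on 1 probe set per gene, the one with the highest mean, over 18193 genes, with Benjamini-Hochberg adjustment over 27 lists (18 functional lists and 9 of cell type markers). The same test with an estimated correlation, fry, and the adjustment over each list alone were run beside it. List scores per array are means of the members' deviations from their average over arrays, compared with exact permutation tests. Members not found under a single symbol were not analysed here.

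The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Hsd11b1, the 12 probe sets with the largest increase and the 12 with the largest decrease among those past the threshold with fully separated groups, filled where fewer pass with the smallest unadjusted p in that direction, 1 probe set per gene. It adds up to 4 members per list with the smallest unadjusted p and, for marker lists, the 3 with the highest mean. As 0 probe sets passed, all 24 were filled by p, and all were fully separated. Other list members named in the report (Hspa1a, Hsph1, Eif2ak3, Asns, Hspa5, Pdia4, Dnajc3, Cish, Tph1, C1qc, Psmb8, Ins2 and Iapp) were chosen after their values were seen.

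Alternatives fixed in advance were a replicate block, leaving out each array in turn, centring on the median, a further quantile normalization, array weights, a trended robust variance, a filter on low signal, other thresholds, a minimum log2 fold change of 1, 1 probe set per gene, an estimated correlation and the mean over a gene's probe sets. The actin 3′/5′ difference as a covariate, leaving out the arrays with low 18S signal, and an estimated correlation together with leaving out KsJ_HF replicate 3 were added after seeing the data.

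The tests were tested on simulated data. With the 4 against 4 comparison's means and spreads over 45037 probe sets and 200 of them changed, limma recovered 0 at a log2 difference of 0.5, 140 at 1 and 182 at 2, with 0, 6 and 11 false calls. Without KsJ_HF replicate 3 it recovered 78, 192 and 199, with 1, 7 and 8 false calls. These simulated probe sets were independent of each other and had the same spread in every array. They therefore held no deviating array, and the recovery does not carry over directly to the real arrays. The adjustment is also easier to pass when 200 probe sets change at once than when few do. Camera recovered a shift of 0.3 in the heat shock list in 50 of 50 runs over 18193 genes, with 1 false call among 1300 tests of other lists; the simulated genes were independent of each other, so this does not cover correlated genes.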

Results

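Pancreatic islets of high-fat-fed mice were profiled to ask what an extra dose of HSD11B1 in beta cells changes in islet gene expression. HSD11B1 is the enzyme that regenerates active glucocorticoid from its inactive 11-keto form. The 8 Affymetrix mouse arrays comprised 4 from wild-type mice, KsJ by their genotype label (KsJ_HF), and 4 from mice heterozygous for the MIP-HSD1 transgene (MIP_HF), all males on a diet with 58% of energy as fat that began at the age of 4 weeks and lasted 12 weeks. Each array held RNA from a separate pool of about 500 hand-picked islets from at least 3 mice. The tissue label names beta cells, while the protocol describes whole islets. Transcripts of other cell types read high: beside Ins2 at 14.96 ± 0.06 (log2 signal, SD, n = 4) in KsJ_HF, the alpha cell hormone Gcg stood at 14.50 ± 0.05 and the acinar enzyme Cela3b at 14.75 ± 0.03. Signals so near the top of the range do not give the share of each cell type. The strain label names C57/Bl6J for all samples, while the genotype label of the wild-type samples names KsJ, which the group name follows. If the groups differed in background strain, these arrays cannot separate that from the transgene. The number of arrays limits the precision.

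Hsd11b1 itself was 3.53-fold higher in MIP_HF islets. Its 1 probe set had a log2 signal of 8.35 ± 0.69 (SD, n = 4) in KsJ_HF and 10.18 ± 0.40 (SD, n = 4) in MIP_HF. The KsJ_HF arrays read 8.18, 8.59, 7.50 and 9.15 and the MIP_HF arrays 10.32, 10.58, 9.63 and 10.17, so that every MIP_HF array lay above every KsJ_HF array. The difference of 1.82 (SE 0.34) had a limma unadjusted p of 0.000484, the smallest of all probe sets, and an adjusted p of 0.842, which is not past the threshold. Whether this probe set lies within the transgene's sequence is not given in the sources used here, so it checks the labels only if it does. Within the 6 arrays of high 18S signal described below, 2 KsJ_HF against 4 MIP_HF, the difference was 1.85.

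The other 11 genes with the smallest p among those higher in MIP_HF differed by modest amounts. Pde5a, the cGMP phosphodiesterase, was 1.76-fold higher (log2 difference 0.82, SE 0.16), and its other probe sets read at least 0.48 higher. The stress-induced Nupr1, at 11.19 ± 0.15 (SD, n = 4) in KsJ_HF and 11.70 ± 0.13 in MIP_HF, was 1.42-fold higher, with 0.51 on both of its probe sets. Hsd17b12, an enzyme of very long chain fatty acid elongation, was 1.28-fold higher (0.35, SE 0.07). Hook3, a microtubule adaptor, was 1.44-fold higher with all 4 probe sets above 0, and the guanylate cyclase receptor Gucy2c was 1.39-fold higher. The integrated stress response regulators Atf4 and Trib3 were also among the 12, at 0.76 and 0.74. For Atf4 the probe sets disagreed, from -0.21 to 0.76, with 0.21 on the brightest, while both Trib3 probe sets were higher, at 0.59 and 0.74. The others were Dock10, Srsf11, Uxs1 and Mapt. Other probe sets of Srsf11, Uxs1 and Mapt read as low as -0.02, -0.17 and -0.05. The selected probe sets of Dock10, Srsf11 and Uxs1 lay near the floor, at mean signals of 3.76, 3.67 and 3.97. The brightest Srsf11 probe set differed by 0.04.

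The 12 genes lowest in MIP_HF by the same rule differed by 1.23-fold to 1.46-fold. Ppat, which catalyses the first committed step of purine synthesis, was lower by 0.55 on the log2 scale (log2 difference -0.55, SE 0.11), although another of its probe sets differed by -0.03. The leukotriene and prostaglandin reductase Ptgr1 stood at 6.16 ± 0.11 (SD, n = 4) in KsJ_HF and 5.73 ± 0.08 in MIP_HF, a difference of -0.43. The transcription factor Usf1 differed by -0.48 (-0.06 on a brighter probe set), the mitochondrial protein Alkbh7 by -0.46, and H2-DMa, which loads peptide onto class II molecules, by -0.43. Fibp, Adprhl2, Pomt2, Pqbp1, Bend5, E130307A14Rik and Flot1 completed the 12, between -0.44 and -0.30. One other Pqbp1 probe set was 0.11 higher, and a brighter Pomt2 probe set differed by -0.06.

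None of these genes passed the threshold. Of 45037 probe sets tested with limma, 0 reached an adjusted p below 0.05 in either direction, and the smallest adjusted p was 0.842. At an unadjusted p below 0.05 there were 1475 probe sets, 950 higher and 525 lower in MIP_HF, against 2252 that chance would give. All 4 arrays of one group lay beyond all 4 of the other for 1281 probe sets, 2.84% of the total, where chance gives 2.86%. The count at unadjusted p depended on single arrays: 2807 probe sets lay below 0.05 without KsJ_HF replicate 3 (1289 higher and 1518 lower, so the excess of higher ones was not kept), 2946 without KsJ_HF replicate 4 and 788 without MIP_HF replicate 2, with 0 past the adjusted threshold each time.

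**Figure D1:**
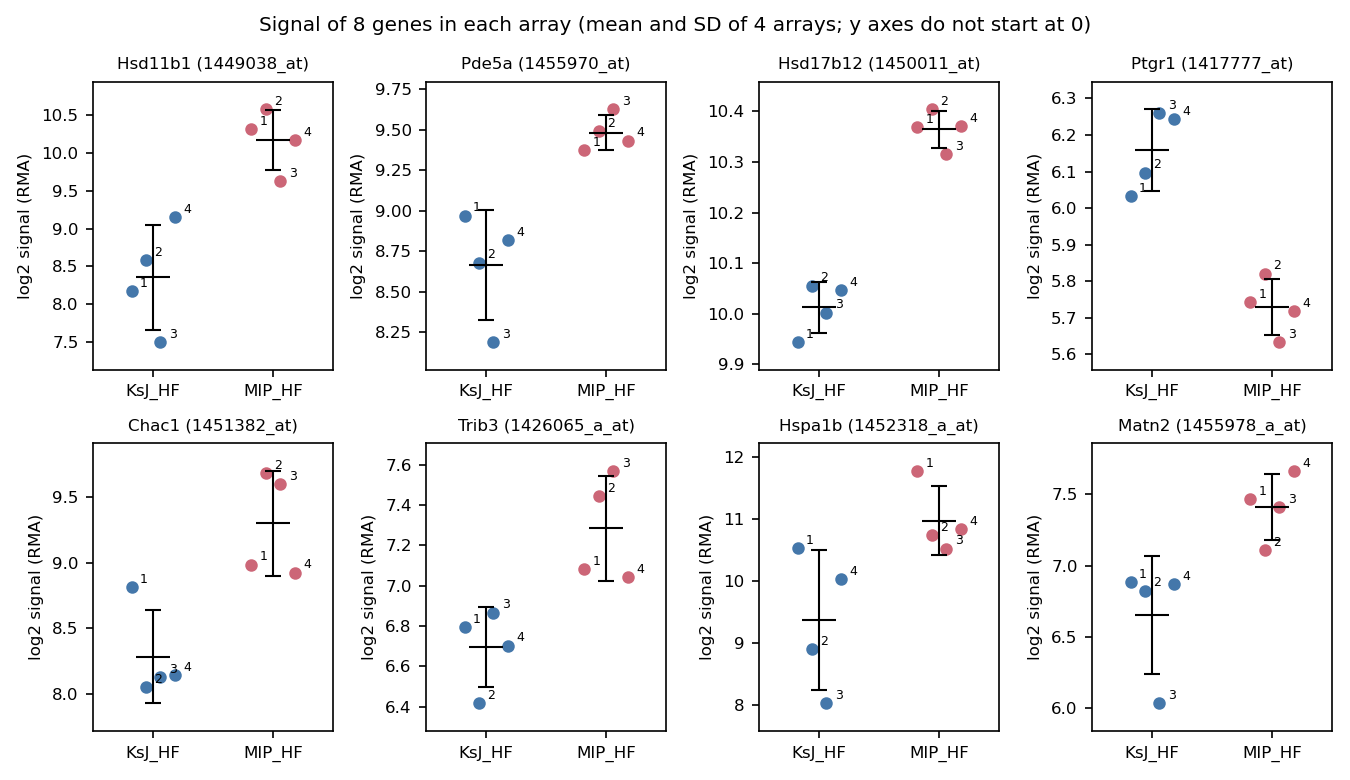
Log2 signal (y axis, RMA values, not starting at 0) of 8 genes in each array, KsJ_HF in blue and MIP_HF in red, with small numbers for the replicates and bars for the mean and SD of 4 arrays. Hsd11b1 lay between 7.50 and 9.15 in KsJ_HF and between 9.63 and 10.58 in MIP_HF, while KsJ_HF replicate 1 overlapped the MIP_HF arrays for Hspa1b.

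Chaperone genes were higher in MIP_HF as groups. Of 22 measured cytosolic heat shock chaperones, 21 were higher, with a median log2 difference of 0.41, and of 30 ER chaperone and unfolded protein response genes 27 were higher, with a median of 0.21. In the first list the inducible Hsp70 genes Hspa1a and Hspa1b were higher by 1.69 (SE 0.62) and 1.60 (SE 0.52), Hsph1 by 0.75, Chordc1 by 0.53, Hsp90aa1 by 0.46 and Hspa4 by 0.41. In the second list Chac1, a glutathione-degrading enzyme, was 2.03-fold higher (1.02, SE 0.23), with Trib3 at 0.59, Ern1 at 0.42, Eif2ak3 at 0.39, Ddit3 at 0.36 and Asns at 0.30. Hspa5 and Pdia4 differed by 0.07 and -0.03.

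Both lists shifted upward by camera with a preset inter-gene correlation, at adjusted p = 1.31e-07 for the heat shock list and 2.21e-07 for the ER list over 27 lists. With an estimated correlation neither call held, at adjusted p = 0.779 and adjusted p = 0.665. No member passed the threshold, over all probe sets or adjusted over the list alone. KsJ_HF replicate 1 scored 0.23 on the heat shock list, as a mean deviation from each gene's average over arrays, within the MIP_HF range of 0.15 to 0.38, so the groups overlapped. The exact two-sided permutation p of that score was 0.114, or 0.617 after Benjamini-Hochberg adjustment over the lists. On the ER list every MIP_HF array scored above every KsJ_HF array, by a mean of 0.21, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 can give, and 0.257 after Benjamini-Hochberg adjustment over the lists. Without KsJ_HF replicate 3 the medians were 0.28 and 0.14, and Trib3, Chac1 and Dnajc3 passed the threshold adjusted over the list alone, at 0.0149, 0.0149 and 0.0472.

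**Figure D2:**
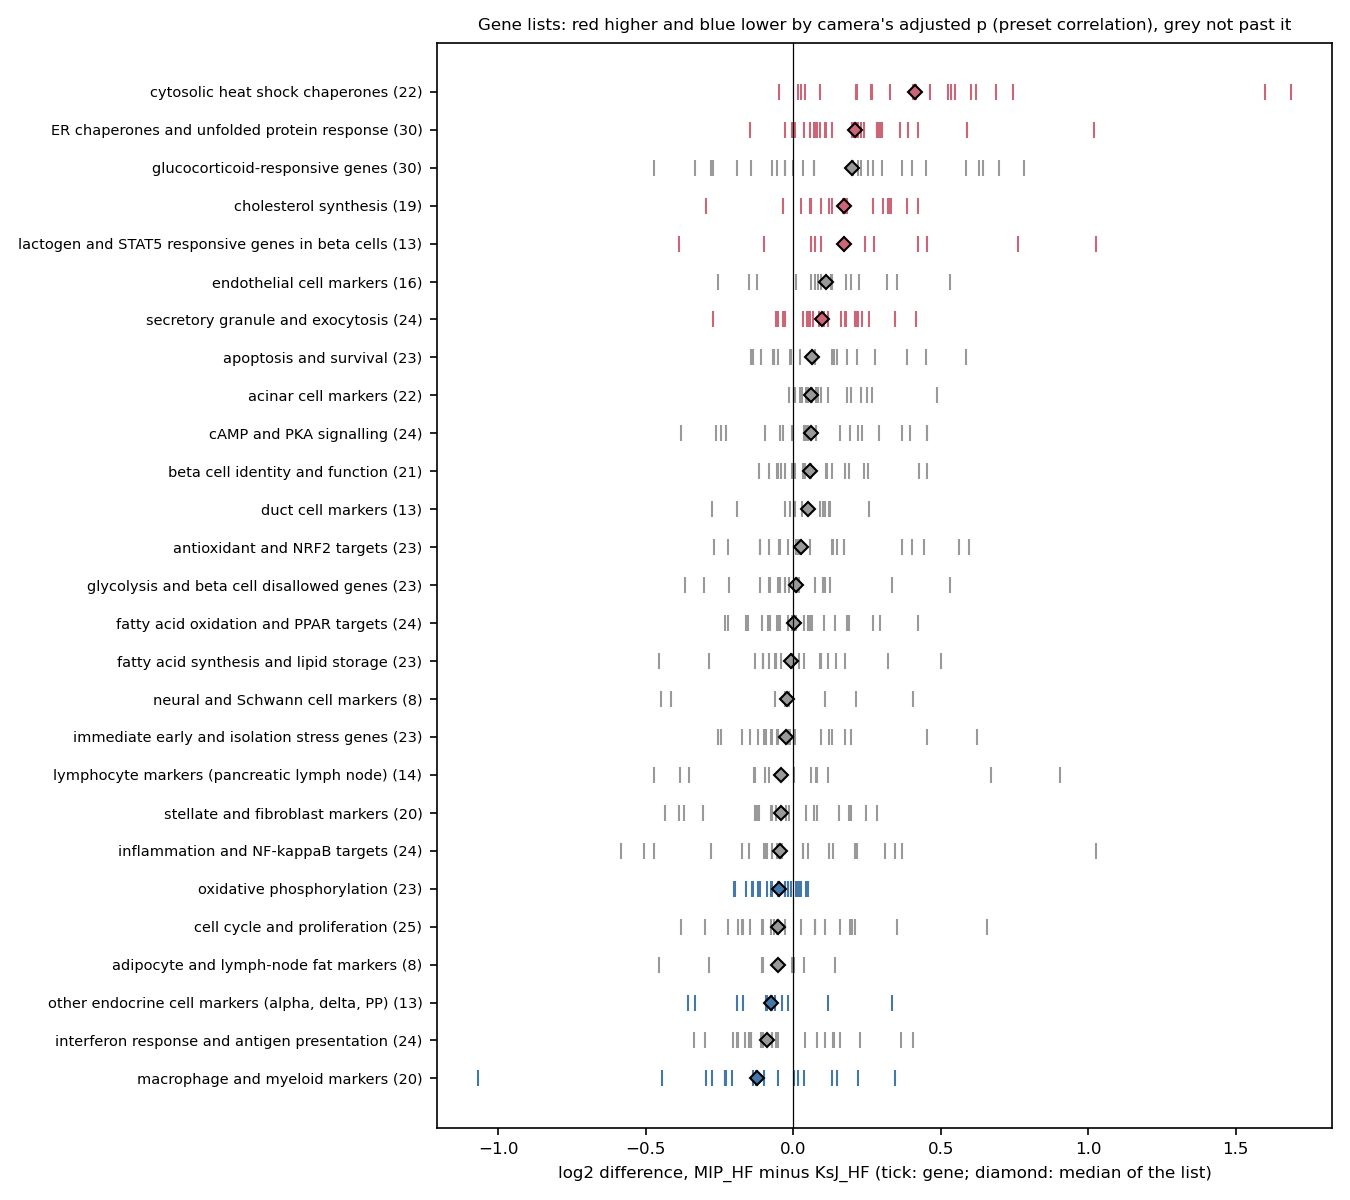
Log2 difference, MIP_HF minus KsJ_HF (x axis), of each measured gene (ticks) in the 27 gene lists (rows, with the number of genes measured), with the median as a diamond. Red lists were higher and blue lists lower by camera's adjusted p with a preset correlation, and grey lists were not past it; the heat shock list had the highest median, 0.41, and the macrophage list the lowest, -0.12.

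The lactogen and STAT5 responsive list also shifted upward, with 11 of 13 genes higher and a median of 0.17. The matrix protein gene Matn2 was 1.69-fold higher (0.76, SE 0.21), and the cytokine signalling suppressors Socs2 and Socs3 were higher by 0.45 and 1.03. Other Socs3 probe sets differed by 0.16, at a mean signal of 5.79 against 6.30 for the one used, and by 0.83. Igfals was higher by 0.27, while the serotonin synthesis gene Tph1 differed by -0.39 near the lower end of the signal range. Camera's adjusted p was 0.0141 with the preset correlation and adjusted p = 0.665 with an estimated correlation. Every MIP_HF array scored above every KsJ_HF array on this list, with an exact two-sided permutation p of 0.0286, or 0.257 after adjustment over the lists. Adjusted over the list alone 0 genes passed; without KsJ_HF replicate 3 there were 5, Matn2, Cish, Igfals, Socs2 and Socs3, with Socs3 at 0.55. The median was then 0.07, less than 0.5 of the full one, with 8 of 13 genes higher, and the estimated correlation gave an adjusted p of 0.515. The mean difference of the list score without that array was 0.17 (SE 0.04), against 0.24 (SE 0.08) in the full comparison. Without KsJ_HF replicate 2 the list did not pass (adjusted p 0.0708).

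Upward shifts were also found for cholesterol synthesis and for secretory granule genes. In the first, 17 of 19 genes were higher with a median of 0.17, led by the SREBP regulator Insig1 (0.42, SE 0.13) and the sterol oxidase Msmo1 (0.38), with Dhcr7 at 0.17. In the second, 18 of 24 were higher with a median of 0.10, among them the prohormone convertase Pcsk1 (0.23, SE 0.07), the active zone gene Pclo (0.35), Unc13a (0.22) and Cpe (0.18). The adjusted p values from camera were 0.00703 and 0.0185, and both lists had adjusted p = 0.779 with an estimated correlation. Their scores had exact two-sided permutation p values of 0.2 and 0.229. Without KsJ_HF replicate 3 the cholesterol list was no longer past the threshold, at 0.215 with a median of 0.06. The secretory granule list was not past it without KsJ_HF replicate 1 or 2 or MIP_HF replicate 1, with a highest adjusted p of 0.216.

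Respiratory chain genes and markers of other endocrine cells and of myeloid cells shifted downward. Oxidative phosphorylation genes were lower in 17 of 23 cases by a median of only 0.05 (log2 difference -0.05), with Cox4i1 at -0.20 and Sdhb at -0.20. Among markers of other endocrine cells, 11 of 13 were lower with a median of -0.08: Ghrl differed by -0.36, Npy by -0.33 and Pyy by -0.17, whereas the hormones Gcg, Sst and Ppy differed by -0.02, -0.06 and -0.09. Macrophage and myeloid markers were lower in 13 of 20 cases with a median of -0.12, with Tyrobp at -0.30, Ctss at -0.23, Lyz1 at -0.23 and C1qa at -0.23. Camera's adjusted p was 0.026, 0.0186 and 0.0219, and for each of the lists adjusted p = 0.779 with an estimated correlation. Adjusted over the list alone 0 genes of any of them passed, and without KsJ_HF replicate 3 Npy, Ghrl, Tyrobp, C1qa and C1qc did. On the myeloid list every MIP_HF array scored below every KsJ_HF array, with an exact two-sided permutation p of 0.0286, or 0.257 after adjustment over the lists. The same test gave unadjusted values of 0.486 for oxidative phosphorylation and 0.314 for the endocrine markers. With the actin 3′ minus 5′ difference described below as a covariate, the myeloid median was 0.10 and the score difference -0.01 in place of -0.13, and within the 6 arrays of high 18S signal the median was 0.005. Leaving out single arrays moved the medians between -0.10 (without KsJ_HF replicate 3) and -0.0042 (without KsJ_HF replicate 2) for oxidative phosphorylation, between -0.14 (without KsJ_HF replicate 1) and -0.03 (without KsJ_HF replicate 4) for endocrine markers, and between -0.16 (without MIP_HF replicate 3) and -0.06 (without KsJ_HF replicate 1) for myeloid markers. It also ended each of these calls: KsJ_HF replicate 2 or 4 or MIP_HF replicate 1 or 2 for oxidative phosphorylation (highest adjusted p 0.373), KsJ_HF replicate 4 or MIP_HF replicate 1 for the endocrine markers (0.358), and KsJ_HF replicate 1 or 2 or MIP_HF replicate 2 for the myeloid markers (0.272).

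Glucocorticoid-responsive genes, the group closest to the enzyme's activity, did not pass the threshold. Of 30 genes 19 were higher, with a median of 0.20 and an adjusted p of 0.0589 from camera. Ddit4, an mTOR inhibitor, was 1.72-fold higher (0.78, SE 0.30), Cebpb was higher by 0.70 (SE 0.26; 0.40 without KsJ_HF replicate 3), and the metallothioneins Mt1 and Mt2 by 0.40 and 0.37, all below an unadjusted limma p of 0.05 and none past an adjusted one in the full comparison. The list score ranged from -0.02 to 0.19 in MIP_HF and from -0.30 to 0.17 in KsJ_HF, with an exact two-sided permutation p of 0.314. The mean difference of the score was 0.16 (SE 0.13), and 0.08 (SE 0.13) without KsJ_HF replicate 3. Leaving out KsJ_HF replicate 3 or 4 or MIP_HF replicate 2 or 4 brought the list past the threshold, at an adjusted p as low as 0.0118, and without KsJ_HF replicate 3 Cdkn1a and Cebpb passed adjusted over the list alone. Leaving out another array could also raise the adjusted p, as given below. The list median was 0.08 without KsJ_HF replicate 2 and only 0.07 without KsJ_HF replicate 3. With an estimated correlation and without KsJ_HF replicate 3 the adjusted p was 0.707.

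Beta cell genes did not pass either, with 14 of 21 higher and a median of 0.06 at an adjusted p of 0.123. Ins2 stood at 14.96 ± 0.06 (SD, n = 4) in KsJ_HF and 14.97 ± 0.02 in MIP_HF and Iapp at 14.73 ± 0.04 and 14.73 ± 0.02, near the top of the signal range, where differences are compressed. G6pc2 was higher by 0.24 (SE 0.08), Nkx6-1 by 0.43 and Glp1r by 0.45 (0.20 without KsJ_HF replicate 3). Without KsJ_HF replicate 3 the list passed at an adjusted p of 0.0199 with a median of 0.03, but not with an estimated correlation (0.627). With the actin covariate its median was -0.05 with 9 of 21 genes higher, and within the 6 arrays of high 18S signal 10 of 21 were higher. Acinar cell genes were higher in 21 of 22 cases but by a median of 0.06 (adjusted p 0.0589), with Amy1 at 0.49, Reg1 at 0.23, Pnliprp2 at 0.25 and Cpb1 at 0.05. The acinar median was 0.02 with 14 of 22 higher without KsJ_HF replicate 4, and 0.11 without KsJ_HF replicate 1. The acinar score difference, 0.11 (SE 0.10), was 0.34 (SE 0.07) with the actin covariate and 0.24 (SE 0.06) within the 6 arrays of high 18S signal. Without KsJ_HF replicate 1 or 3 or MIP_HF replicate 1 that list passed, at 0.000325 without KsJ_HF replicate 1, and with an estimated correlation it did not (0.78 in the full comparison, 0.758 without KsJ_HF replicate 3). Interferon and antigen presentation genes were lower in 15 of 24 cases with a median of -0.09 (adjusted p 0.123). Irf7 differed by -0.34 and H2-Ab1 by -0.30 (-0.04 and -0.24 on its other probe sets). For the interferon genes the median ran from -0.14 without KsJ_HF replicate 3 to -0.04 without KsJ_HF replicate 4. They passed at 0.00123 without KsJ_HF replicate 3, where H2-Ab1, Psmb9 and Psmb8 passed adjusted over the list alone, and also without MIP_HF replicate 3. With an estimated correlation they did not pass without KsJ_HF replicate 3 (0.532), and with the actin covariate their median was 0.02 with 16 of 24 genes higher and H2-Ab1 at 0.0058 (-0.08 within the 6 arrays of high 18S signal). Endothelial markers had a median of 0.11 (adjusted p 0.112), with Plvap at 0.32 and Emcn at 0.22, and passed at 0.00694 without MIP_HF replicate 3, while the full comparison with an estimated correlation gave 0.779. Leaving out single arrays moved the endothelial median between 0.05 (without MIP_HF replicate 1) and 0.17 (without MIP_HF replicate 3).

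The remaining lists showed no shift by camera. Their adjusted p was 0.692 for fatty acid oxidation (Cd36 at -0.23, Plin2 at 0.29), 0.649 for fatty acid synthesis and lipid storage (Fads1 at 0.50), 0.692 for glycolysis and disallowed genes (Zfp36l1 at 0.53), 0.483 for cAMP signalling (Adcy6 at -0.23) and 0.649 for immediate early and isolation stress genes (Fos at 0.62, Zfp36 at -0.25). It was 0.272 for antioxidant and NRF2 targets (Nqo1 at 0.56, Gclc at 0.44), 0.7 for inflammation and NF-kappaB targets (Il1r1 at 0.34), 0.272 for apoptosis and survival (Cdkn1a at 0.58), and 0.7 for cell cycle genes, where Mki67 at 0.20 and Cdk1 at 0.35 stood against a list median of -0.05. Marker lists of duct cells (0.692, Krt19 at -0.19), stellate cells and fibroblasts (0.272, Col6a3 at -0.37), lymphocytes (0.483, Cd2 at -0.38), adipocytes (0.272, Lipe at -0.46) and neural cells (0.93, Cdh19 at 0.40) did not pass. For the cell cycle, fatty acid oxidation, fatty acid synthesis, glycolysis, immediate early, inflammation and lymphocyte lists the median, the mean and camera's direction differed in sign. With an estimated correlation or with fry 0 of 27 lists passed.

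Array quality measures varied among the arrays, and for 18S and actin the ranges of the groups overlapped only narrowly. The highest KsJ_HF values were 12.62 for 18S and 1.739 for the actin 3′ minus 5′ difference, against lowest MIP_HF values of 12.61 and 1.733. KsJ_HF replicate 3 correlated with the other arrays at r = 0.942 to 0.949 over probe sets, which are not independent replicates, where the other 7 correlated with each other at up to 0.996, and its poly-A spike controls were at 5.98 against 6.63 to 7.18. The 18S rRNA controls were low in KsJ_HF replicates 1 and 2, at 10.74 and 10.75, against 12.43 to 12.99 in the other 6 arrays; between groups the mean difference of 1.19 had an exact two-sided permutation p of 0.0571. The 3′ minus 5′ difference of the actin control was 1.51 ± 0.20 (SD, n = 4) in KsJ_HF and 1.78 ± 0.05 in MIP_HF, with an exact two-sided permutation p of 0.0571. Within the 6 arrays of high 18S signal the heat shock list kept a median of 0.44 (camera adjusted p 1.59e-06) and the ER list 0.20 (0.000228), and the cholesterol and endocrine marker lists passed at 0.0115 and 0.0186. The lactogen list (0.292) did not pass there although its median was 0.18 against 0.17 in the full comparison. The secretory granule list (0.627, median 0.06), oxidative phosphorylation (0.788, median -0.02) and the myeloid markers (0.788, median 0.005) did not pass either, while acinar (0.000623) and stellate markers (0.0186) did. The low-18S arrays were KsJ_HF arrays only, so the KsJ_HF side of this fit held replicates 3 and 4, and the deviating replicate 3 weighed more. These 2 arrays scored -0.69 and -0.04 on the heat shock list. On the cholesterol list they scored -0.46 and 0.11, against a MIP_HF mean of 0.08. On the stellate list they scored -0.09 and 0.37, against -0.15 to 0.07 in MIP_HF, so that call rested on replicate 4. The stellate score difference within the 6 arrays was -0.16 (SE 0.16). Without KsJ_HF replicate 4 alone left out of the full comparison, the stellate median was 0.06. All calls within the 6 arrays rest on the preset correlation, and an estimated one was not run there. KsJ_HF replicate 3 also weighed on single genes: without it the difference was 1.12 for Hspa1a, 0.21 for Msmo1, 0.15 for Fads1, 0.28 for Zfp36l1, 0.29 for Fos, 0.34 for Nqo1, 0.21 for Gclc, 0.28 for Amy1, 0.13 for Emcn, 0.19 for Cdh19, -0.14 for Tph1, -0.18 for Lipe, -0.21 for Irf7 and -0.21 for Cd2, each at least 1.5 times smaller than with it. It was at least 1.5 times larger for Cish (0.52 against 0.24), C1qa (-0.37 against -0.23), C1qc (-0.37 against -0.21), Psmb9 (-0.31 against -0.21) and Psmb8 (-0.27 against -0.10).

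**Figure D3:**
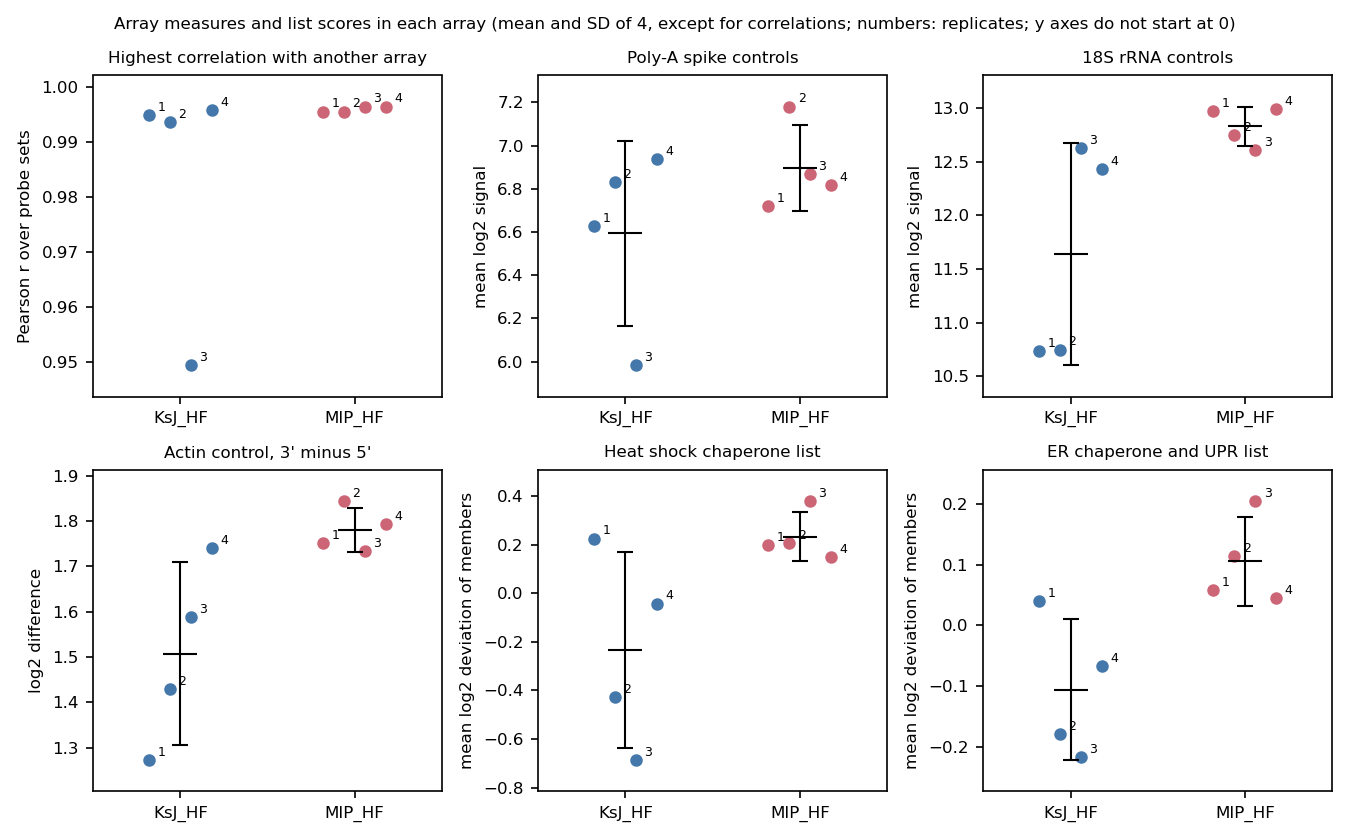
Array measures and list scores (y axes, not starting at 0) for each of the 4 KsJ_HF (blue) and 4 MIP_HF (red) arrays, with small numbers for the replicates and bars for the mean and SD of 4 except for the correlations. KsJ_HF replicate 3 stands apart in correlation, at 0.949, and in poly-A spikes, at 5.98, while KsJ_HF replicates 1 and 2 are low in 18S signal, at 10.74 and 10.75.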

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

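The tests on KsJ_HF replicate 3 reported here were chosen after the result was seen, as were the test without that array, the test on immediate early genes for the chaperone lists and the test on Tph1, whose criterion was reworded once its value was known; the counts over other splits and the tests with the actin covariate were set out before their results were seen.

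In groups of 4 arrays, a sample far from the other 3 was found in 19 of 344 groups tested (18 for genes, 1 for a list score), where chance gives about 5%. Of these, 11 were KsJ_HF replicate 3. It was low for Rrm2 (3.23, others from 4.56), Socs3 (4.37, others from 6.19) and Matn2 (6.03, others from 6.82). It was high for Lipe (5.30), Acacb (5.73), Tlr4 (5.49), Saa1 (5.64), Mrc1 (5.12), Cd3g (4.68), Adipoq (4.29) and S100b (6.06), where the other KsJ_HF arrays read at most 4.19, 4.79, 4.25, 4.07, 3.90, 3.56, 4.11 and 4.48. Ighm was high in MIP_HF replicate 4 (9.18, others up to 7.21), as was Emcn (9.28, others up to 9.12), and Slc2a4 was low there (4.46, others from 4.62). The remaining ones were Chac1 in KsJ_HF replicate 1 (8.81, others up to 8.14), Socs2 in KsJ_HF replicate 4 (7.85, others up to 7.42), Tm7sf2 in MIP_HF replicate 1 (6.29, others up to 6.14), Kdr in MIP_HF replicate 3 (8.09, others from 8.496) and the adipocyte list score in MIP_HF replicate 3 (0.00596, others up to -0.0587). In control probe sets outside the gene comparison, the 18S signal was higher in MIP_HF by 1.19 and the actin 3′ minus 5′ difference by 0.27.

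KsJ_HF replicate 3 stands apart from all other arrays. Against the other KsJ_HF arrays it had 132 probe sets at least 2 log2 units higher and 173 at least 2 lower, where another KsJ_HF array against the remaining 2 had at most 9 and 4. RNA degradation is argued against by an actin 3′ minus 5′ difference of 1.59, within the 1.27 to 1.84 of the others, although the Gapdh difference of 0.26 was above the 0.05 to 0.08 of the other KsJ_HF arrays, because MIP_HF replicate 2 had higher values of both (1.84 and 0.42) and correlated at up to 0.996. Other cells in the sample stay open: the 230 other probe sets of the raised genes deviated by a median of 0.0549, with 2 of them at least 2 higher, but adipocyte and neural markers had medians of 0.24 and 0.28, within their spread, and myeloid markers -0.44. Weak labelling stays open and may account for it: poly-A spikes were at 5.98, below all other arrays, with hybridization spikes at 10.17 inside their range, though a smaller spike volume would look alike and no biological explanation was tested.

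The chaperone lists were higher in MIP_HF. Without the deviating array camera's adjusted p was 1.09e-06 for the heat shock and 3.62e-07 for the ER list. With the actin difference as a covariate it was 4.22e-09 and 3.33e-06, with medians of 0.50 and 0.24 against 0.41 and 0.21 before. These p values rest on the preset correlation, at which splits that mixed the groups gave the heat shock list values as small. They therefore exclude neither the array nor RNA integrity. The heat shock score difference was 0.31 (SE 0.17) without KsJ_HF replicate 3 and 0.66 (SE 0.31) with the covariate. For the ER list it was 0.17 (SE 0.07) and 0.28 (SE 0.10). Both lists stayed upward, but the covariate ran close to the groups, and with it the acinar score also rose, by 0.34 (SE 0.07). With an estimated correlation both chaperone calls were lost in the full comparison (0.779 and 0.665) and without KsJ_HF replicate 3 (0.59 and 0.515). For the heat shock list 4 of the 35 splits of the arrays into 4 and 4 gave a camera p as small (real split 4.85e-09, smallest other 6.2e-15). The other 3 of them placed KsJ_HF replicate 1 with MIP_HF arrays, so chance cannot be excluded. For the ER list 1 of 35 did (1.64e-08, smallest other 2.56e-08), the smallest share that 35 splits can give. This argues against chance for the list taken alone, but excludes it neither there nor for a choice among 27. Handling stress of isolated islets stays open, as the immediate early list had a median of -0.0255 over members that went both ways. The transgene and a difference in background strain stay open too. A biological origin is a hypothesis that these arrays cannot separate from sample handling.

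The lactogen list was higher in MIP_HF, and a lactogenic hormone acting on beta cells may raise such genes. Tph1, the expected strongest responder, differed by -0.39 with an upper 95% bound of 0.12, but its signal of 3.32 to 4.57 lies near the floor, so this test decides nothing. The list passed neither with the actin covariate (0.197) nor without the low-18S arrays (0.292). The mean difference of its score, 0.24 (SE 0.08) before, was 0.27 (SE 0.14) and 0.29 (SE 0.12), so the spread grew. Without the low-18S arrays the KsJ_HF side held replicates 3 and 4 only, which scored -0.35 and 0.02 against 0.05 to 0.17 in MIP_HF. The deviating replicate 3 weighed more there, so these fits decide neither for nor against RNA quality. The labels do not describe the transgene's sequence.

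Other splits of the 8 arrays bear on the counts. For the 0 probe sets past the threshold all 35 of 35 splits necessarily gave as many (highest other 0), so this count says nothing about chance. For probe sets at unadjusted p below 0.05, 7 of 35 gave at least the real 1475 (highest other 3109), so chance cannot be excluded. The split with 3109 placed KsJ_HF replicates 1 and 3 with MIP_HF replicates 1 and 2 and called over 2 times the real count, so differences among the samples unrelated to the groups may outweigh the group difference. For gene lists past the threshold, 3 of 35 gave at least the real 8 (highest other 9), so chance cannot be excluded.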

How the results depend on the processing

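The actin covariate, the fit without the 2 arrays of low 18S signal and the estimated correlation without KsJ_HF replicate 3 were chosen after seeing the data. The count of 0 differentially expressed probe sets held under every alternative run, including adjusted p below 0.1 and 0.01, a minimum log2 fold change of 1 and 1 probe set per gene, with limma the only tool. Hsd11b1 was higher in MIP_HF under every alternative, by 1.43 (actin covariate) to 2.09 (without KsJ_HF replicate 4), and past the adjusted threshold under none. The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.12, -0.16, -0.13 and 0.19. With the replicate number as a block 0 probe sets and 8 lists passed, 1071 lay at unadjusted p below 0.05, Hsd11b1 differed by 1.82, and the block changed no list's call. Over all alternatives, list results kept direction and side of the threshold 409 times, turned direction 38 times, newly passed 25 times and were lost 41 times, and gene results kept their direction 2242 times and turned 55 times, none past the threshold. Unless stated, causes were not tested.

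With an estimated correlation 0 lists passed in place of 8: camera's adjusted p became 0.665 for the ER and lactogen lists and 0.779 for the heat shock, cholesterol, secretory granule, endocrine, oxidative phosphorylation and myeloid lists. Without KsJ_HF replicate 3 as well it was 0.515 for the ER, lactogen and myeloid lists, 0.59 for heat shock and oxidative phosphorylation, 0.627 for endocrine, 0.695 for cholesterol and 0.707 for secretory granule genes, and direction turned for cell cycle and inflammation (0.839), duct (0.843) and neural (0.692) lists. In the full comparison the estimated correlations were 0.54 for heat shock, 0.46 for oxidative phosphorylation, 0.41 for cholesterol and 0.29 for endocrine genes. They were 0.28 for secretory granule, 0.20 for ER, 0.12 for myeloid and 0.03 for lactogen genes. All lie above the preset of 0.01. A higher correlation raises the variance that camera allows for a list, so the p values at the preset correlation were too small if these estimates hold.

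The values below are camera's adjusted p for lists and log2 differences for genes, and no gene was past the threshold. With array weights the cholesterol list was lost (0.0963), the acinar (0.0337), beta cell (0.0129) and interferon (0.000856) lists passed, and direction turned for cell cycle (0.592), duct and inflammation (0.783) and neural (0.409) lists and for Car3 (-0.044), Cela3b (-0.0021), Epcam (-0.0074), Krt18 (-0.027) and Tubb3 (0.079). With quantile normalization the interferon list passed (0.0394), and direction turned for cell cycle (0.985) and inflammation (0.869) lists and for Epcam (-0.0055), Kdr (-0.0103), Krt18 (-0.041), Retn (-0.038) and Sparc (-0.037). With median centring the acinar list passed (0.0279), oxidative phosphorylation was lost (0.0769) and Gcg turned (0.0035). With a trended robust variance the acinar (0.00645) and glucocorticoid (0.0347) lists passed. With the mean of a gene's probe sets the acinar and beta cell (0.0128) and glucocorticoid (0.0422) lists passed, oxidative phosphorylation was lost (0.137), and the cell cycle and fatty acid oxidation (0.749) and inflammation (0.971) lists turned. With the low-signal filter the secretory granule list was lost (0.129) and the adipocyte (0.903), duct (0.715) and inflammation (0.596) lists turned.

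With the actin covariate the lactogen (0.197, median 0.18 against 0.17 before), oxidative phosphorylation (0.381, -0.06 against -0.05) and secretory granule (0.635, 0.01 against 0.10) lists were lost, the acinar (3.11e-09) and stellate (0.000444) lists passed, and direction turned for the beta cell and immediate early (0.785), cell cycle and myeloid (0.901), endothelial (0.828), inflammation (0.635) and lymphocyte (0.986) lists and for Car3 (-0.0012), Cd52 (0.21), Epcam (-0.079), H2-Ab1 (0.0058), Il1r1 (-0.063), Krt18 (-0.00036), Retn (-0.047), Sparc (-0.099) and Uqcrc1 (0.046). Without the low-18S arrays the lactogen (0.292), myeloid and oxidative phosphorylation (0.788) and secretory granule (0.627) lists were lost, the acinar (0.000623) and stellate (0.0186) lists passed, and direction turned for the beta cell list (0.971) and for Cd52 (0.26), Epcam (-0.028), Retn (-0.027), Rgs5 (0.0085), Sparc (-0.0402) and Uqcrc1 (0.0072). These fits have fewer arrays or residual degrees of freedom, and the SE of the lactogen score was 0.14 and 0.12 against 0.08. The stellate score difference was -0.26 (SE 0.16) with the actin covariate and -0.16 (SE 0.16) without the low-18S arrays.

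Leaving out 1 array at a time, between 4 (without KsJ_HF replicate 2) and 11 lists (without KsJ_HF replicate 3) passed. The lowest and highest adjusted p were 0.00201 and 0.215 for cholesterol, 0.00335 and 0.0708 for lactogen, 3.65e-05 and 0.272 for myeloid, 0.00388 and 0.358 for endocrine, 0.000162 and 0.373 for oxidative phosphorylation and 0.00294 and 0.216 for secretory granule lists. They were 0.000325 and 0.92 for acinar, 0.0199 and 0.464 for beta cell, 0.0118 and 0.517 for glucocorticoid, 0.00123 and 0.582 for interferon and 0.00694 and 0.373 for endothelial lists. For lists that only turned direction they were 0.368 and 0.921 (cell cycle), 0.485 and 0.971 (duct), 0.214 and 0.915 (fatty acid oxidation), 0.272 and 0.997 (glycolysis), 0.209 and 0.942 (immediate early), 0.315 and 0.975 (inflammation), 0.246 and 0.994 (neural) and 0.0708 and 0.722 (stellate). Genes that turned ranged from -0.054 to 0.086 (Car3), -0.43 to 0.0078 (Cd52), -0.52 to 0.0051 (Cd8a), -0.0091 to 0.011 (Cela3b), -0.0089 to 0.11 (Epcam), -0.16 to 0.052 (Gap43), -0.0373 to 0.01004 (Gcg), -0.038 to 0.035 (Krt18), -0.46 to 0.0074 (Maf), -0.014 to 0.087 (Retn), -0.19 to 0.0016 (Rgs5), -0.44 to 0.024 (Slc2a4), -0.017 to 0.14 (Sparc) and -0.16 to 0.11 (Tubb3). Probe sets at unadjusted p below 0.05, 1475 in the full comparison, ranged from 788 without MIP_HF replicate 2 to 2946 without KsJ_HF replicate 4, with 2638 under array weights, 784 under the filter, 947 with the actin covariate and 2630 without the low-18S arrays. Signal near the floor of about 3 and the ceiling of about 15 limits what can be seen there.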

Other observations

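Amino acid response genes, a list put together after the data were seen, were higher in MIP_HF in 23 of 27 cases, with a median log2 difference of 0.25. Among them were the transporters Slc38a2 (0.61, SE 0.19), Slc7a5 (0.42, SE 0.12) and Slc7a1 (0.37, SE 0.11), the aminotransferase Gpt2 (0.74, and 0.31 without KsJ_HF replicate 3), the serine synthesis enzyme Phgdh (0.46, and 0.25 without that array) and the translation repressor Eif4ebp1 (0.34), while Slc7a11 differed by -0.02. None passed the threshold adjusted over the list alone. The camera p, unadjusted, was 2.51e-08 with the preset correlation and 0.0756 with an estimated correlation, and 1.03e-07 with a median of 0.15 without KsJ_HF replicate 3. As the list was chosen from these data, this is no independent evidence.

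MIP_HF replicate 4 was high for Ighm, at 9.18 where the other MIP_HF arrays read 6.92 to 7.21, and for Jchain, at 7.50 where they read 4.19 to 4.25. The other 7 genes of a plasma cell list of 9, among them Sdc1 (5.07), Tnfrsf17 (4.22) and Xbp1 (12.37), lay within the range of the other arrays, so no cell type is named from this. The list, also chosen after seeing the data, showed no shift between the groups (camera unadjusted p 0.284).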
